A study of Rattus norvegicus with 244 samples.

How the data were processed

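RNA from 2 brain regions of the rat, the raphe and the somatomotor cortex, was measured on arrays of 3 types, called A, B and C here, that carry different sets of probes. The 244 arrays came from 84 samples, 41 of raphe (119 arrays) and 43 of cortex (125 arrays). Groups were taken from the titles and descriptions, which give the region, the treatment (naive, laminectomy without injury, called sham here, or moderate spinal cord injury), the time and a replicate number. Where the title of an array and its description gave different times, the title was followed. This concerned the type A arrays of replicates 1 and 2 of injured cortex at 24 h, whose descriptions give 4 h, and the raphe sham sample at 30 min. The labels do not say that samples are separate animals, and each was treated as one.

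The deposited values are intensity values, 1 positive signal per probe set on a linear scale, which the authors had scaled per array. The upstream software is not given in the sources used here. The 2 percent trimmed mean of an array lay between 800.5 and 801.3 on every array, and within 0.0447 percent of the median of its array type. Because this met the limit of 5 percent set beforehand, the deposited scaling was kept, 32 was added to each value and the log2 was taken. The number of arrays limits the precision, with 2 sham samples at each time. Signal over background limits it too: the array medians ran from 185.8 to 410.5, and the added 32 draws the differences of weakly expressed genes towards 0.

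Of the 26202 probe sets left without controls, 18178 were matched to a single gene symbol, 391 to several and 7633 to none. A probe set was tested in a region if its value exceeded the 40th percentile of its array on at least 4 arrays of the region. This left 18716 probe sets in the raphe, 18769 in the cortex and 19453 in the fit of both regions. The 59 control probe sets of each type were left out of the tests and used to describe the RNA.

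Group means were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), within each array type and region, with the moderated test of limma and all groups of a region sharing a spread. The Benjamini-Hochberg adjustment was made over the 3 array types together, and the threshold was an adjusted p of 0.05. Comparisons were injured against sham at each of 6 times and as the mean over them, injured against naive, sham against naive, and limma F tests of the change over time of the injured minus sham difference and of the time course of injured samples. In the fit of both regions, the difference between the regions in the injury effect and naive raphe against naive cortex were tested. All tests were two-sided. Changes are given as differences of log2 values with their standard error. Samples that show a direction are those on that side of the mean of the group they are compared with, at the same time where one is given.

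Named genes were chosen by a rule. They have a single symbol, and the probe set with the highest mean signal stands for a gene. Over the 6 times and between naive regions they are the 10 largest rises and 10 largest falls past the threshold, and at each time and for sham against naive the 5 and 5. For the F tests and the difference between regions they are the 10 with the smallest p past the threshold. Where fewer than 5 genes passed, they are those that passed and the 5 with the smallest p, and a gene list can add up to 4 members with the smallest p. Gene lists, 33 in number, covered stress, glial, immune, neuronal and metabolic genes and markers of other cell types and neighbouring tissues that a dissection could hold. They were tested with cameraPR of limma at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. In the text, list members are counted over all genes tested and adjusted over the list alone.

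The groups, the comparisons, the tests, the rule for naming, the gene lists and most alternatives were fixed before the data were examined. Alternatives were quantile normalization, no filter and a stricter filter at the 60th percentile, an added 1 or 128 in place of 32, array quality weights, the replicate number as a block, leaving out each replicate, adjustment within each array type, cortex at 24 h without the arrays of conflicting labels, naive in place of sham samples, and for the lists the mean of all probe sets of a gene. Added after seeing the data were a fit without 5 doubted samples, a fit without 3 of them, a correction for the place of a probe set in identifier order, and covariates from control probe sets and from the highest signal of an array. So were a test of the injured samples at 4 h without a doubted sample and the use of type A genes for samples on type A alone.

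The 5 doubted samples were chosen by rules set after seeing the data. A sample was doubted if the 5th percentile of its signal was at least 2 times the median of its region, if its actin 3' over 5' ratio was at least 4 times that median, or if a region score from 200 probe sets lay nearer to the other region. The score is 0 at the mean of naive cortex and 1 at the mean of naive raphe.

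The steps were tested on simulated data, drawn with the mean and spread of each probe set, with 100 probe sets changed by 1 log2 unit and 100 by 2. For the mean over the 6 times, 95 and 99 percent were found in the raphe and 97 and 100 percent in the cortex. At 7 d, with 4 injured and 2 sham samples, 28 and 86 percent were found in the raphe and 36 and 89 percent in the cortex. No arrays of a type were identical, and the highest correlation between any pair was 0.985. Sham samples at 30 min and at 72 h had no injured counterpart and were left out of the comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.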

Results

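Arrays measured gene expression in the raphe, a brainstem region whose serotonin neurons project to the spinal cord, and in the somatomotor cortex, which holds the neurons of the corticospinal tract. In each region there were 4 naive samples, 24 injured samples (4 at each of 4 h, 24 h, 7 d, 14 d, 28 d and 3 months after a moderate injury) and 12 sham samples (2 at each of these times). On array type A there was only 1 raphe sham sample at 3 months, so 11 in all, and on type C there were 3 naive raphe samples. Beyond these, 1 raphe sham sample and 2 cortex sham samples at 30 min and 1 cortex sham sample at 72 h had no injured counterpart, and those at 30 min were measured on type A alone.

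The naive samples gave the expression that set the regions apart before any operation. In naive raphe, Sncg was higher than in naive cortex by 6.62 ± 0.49 (log2 difference ± SE, n = 4 and 4, adjusted p = 1.2e-16, 4 of 4 samples). Spp1 (4.62 ± 0.40), Chodl (4.61 ± 0.54), Prph (3.89 ± 0.32), an intermediate filament, and Slc17a6 (3.86 ± 0.43), a vesicular glutamate transporter, were also higher. Tppp3, Apobec2, Dao, Calb2 and Lgals1 rose by 3.01 to 3.89. Naive cortex had more of the neuropeptide gene Cck (-5.83 ± 0.33 in raphe against cortex), Nrgn (-5.75 ± 0.27), Arpp21 (-5.70 ± 0.52), Itpka (-5.59 ± 0.19) and Crym (-5.36 ± 0.48). Ddn, Fam107a, Mef2c, Hpcal4 and Ptk2b were lower in the raphe by -4.46 to -3.90. Every one of these 20 genes differed the same way in all raphe samples measured.

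Of the 25 forebrain cortex genes, 0 were higher and 21 lower in naive raphe (23 lower adjusted over the list alone; mean -2.52, adjusted p = 5.3e-36). Of the 19 brainstem genes, 13 were higher and 0 lower (13 over the list alone; mean 1.87, adjusted p = 1.6e-13). Of 18 serotonin and monoamine genes, 10 were higher and 0 lower (11 and 1 over the list alone; mean 0.88, adjusted p = 6.8e-05), among them Dbh (2.73) and Th (1.81), enzymes of catecholamine synthesis, and Gata3 (1.68). Myelin genes were higher in 12 of 22 cases (17 over the list alone; mean 0.92, adjusted p = 1.4e-09). That call was lost at an adjusted p = 0.052 with an estimated correlation. Cholesterol synthesis genes were higher in 7 of 24 cases (11 over the list alone; mean 0.52, adjusted p = 6.8e-05). Lower were 14 of 39 voltage-gated ion channels, with 2 higher (15 and 2 over the list alone; mean -0.66, adjusted p = 1.1e-07), 16 of 38 glutamate receptor and transporter genes, with 1 higher (22 and 1 over the list alone; mean -0.53, adjusted p = 9.1e-07), 11 of 26 immediate early genes (11 over the list alone; mean -0.94, adjusted p = 7.4e-08) and 9 of 33 synaptic vesicle genes, with 4 higher (10 and 4 over the list alone; mean -0.37, adjusted p = 0.0059).

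Also higher on the mean in naive raphe were neuronal cytoskeleton (0.57, adjusted p = 0.0037), heat shock (0.35, adjusted p = 0.011), blood cell (0.71, adjusted p = 0.0022), mitochondrial (0.30, adjusted p = 9.6e-04) and proteasome genes (0.33, adjusted p = 4.8e-04). Of their 25, 26, 8, 78 and 36 members 7, 8, 5, 10 and 8 were higher and 3, 0, 1, 2 and 0 lower, and over each list alone 8, 12, 6, 13 and 8 were higher and 5, 1, 1, 2 and 0 lower. Under an estimated correlation their adjusted p was 0.071, 0.144, 0.095, 0.099 and 0.052, so these calls were lost and 8 of the 14 lists held. The other 19 lists had adjusted p from 0.093. In all, 2770 of 19453 probe sets passed, 1293 higher and 1477 lower in raphe, and 3940 without the samples described next, 2766 of them shared.

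A score built from 200 probe sets of this comparison placed 39 raphe samples between 0.902 and 1.02 and 40 cortex samples between -0.0163 and 0.0708. Raphe injured at 4 h, replicate 1, scored 0.870. The sample labelled raphe sham at 3 months, replicate 1, scored 0.0493, and the sample labelled cortex sham at 3 months, replicate 1, scored 0.654. Cortex sham at 14 d, replicate 2, scored 0.169 and had a 5th percentile of signal of 55.3, against 10.02 to 19.52 in the other cortex samples. Cortex injured at 7 d, replicate 2, had 32.1. Raphe injured at 4 h, replicate 1, had an actin 3' over 5' ratio of 50.0, against 1.25 to 2.59 in the other raphe samples. These 5 samples are called the doubted samples. They were chosen after seeing the data, and the counts are also given without them. None of them belongs to the groups compared in the raphe at 24 h, 7 d, 14 d and 28 d or in the cortex at 4 h, 24 h and 28 d. There, leaving them out acts only through the filter and the spread that all groups share.

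**Figure D1:**
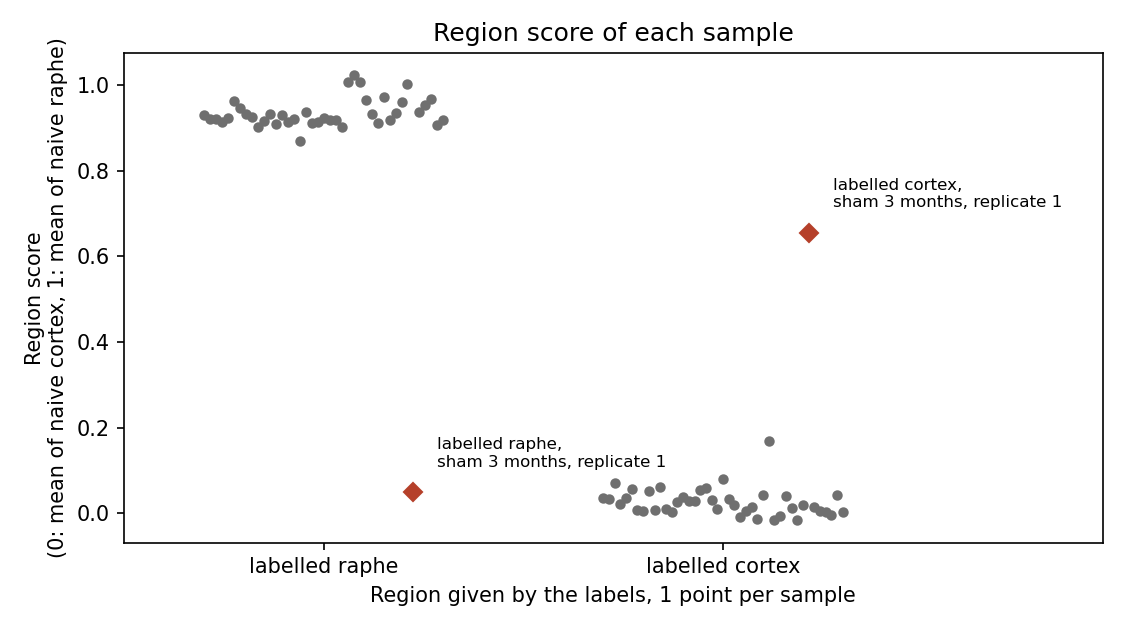
Region score of each sample (vertical axis, no unit, 0 at the mean of naive cortex and 1 at the mean of naive raphe) by the region its label gives, 1 point per sample. The samples labelled raphe and cortex sham at 3 months, replicate 1 of each, sit at 0.0493 and 0.654, away from the other samples of their region.

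Injured against sham raphe over the 6 times asked what changed beyond the laminectomy. S100a11, a calcium-binding protein, was higher in injured raphe by 1.23 ± 0.17 (n = 24 and 12, adjusted p = 3.2e-04, 20 of 24 injured samples). Eva1b was higher by 1.30 ± 0.23 (adjusted p = 0.0043, 20 of 24) and Ccn2 by 0.93 ± 0.19 (adjusted p = 0.012, 17 of 24). Kcne1 rose by 0.95 ± 0.18 (adjusted p = 0.0095, 24 of 24), Dpp4 by 0.97 ± 0.21 and Hspa13 by 0.78 ± 0.17. Eps8, Ier5, Letm2 and Tspan8 rose by 0.80 to 0.97. Kcne1, Dpp4, Eps8, Letm2 and Tspan8 had sham means below the negative controls. Mtmr1, a phosphoinositide phosphatase, fell by 1.00 ± 0.19 (adjusted p = 0.0087, 22 of 24), and Hal, Rab14, Lcmt2, Ap5s1 and Cd40 fell as well (-0.86 to -0.69). Ubqln4 (-0.67 ± 0.12), Plau (-0.58 ± 0.11), a plasminogen activator, Fgd4 (-0.68 ± 0.15) and Suv39h2 (-0.58 ± 0.15) fell too. The 10 that fell did so in 18 to 23 of 24 injured samples. All 20 genes also passed without the doubted samples. With 1 sample left out, 12 of the 20 did not pass at least once, Letm2, Rab14, Lcmt2 and Suv39h2 among them (adjusted p up to 0.106, 0.099, 0.114 and 0.092), and 8 always passed. Suv39h2 was also lost with a correction for place in identifier order (adjusted p = 0.105).

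Some of the raised genes were lower in sham than in naive raphe. S100a11 differed from naive raphe by -0.05 in injured samples (adjusted p = 0.96) and by -1.28 in sham samples (adjusted p = 0.030). For Dpp4 these values were -0.54 (adjusted p = 0.38) and -1.50 (adjusted p = 0.015), and for Tspan8 -0.70 (adjusted p = 0.17) and -1.50 (adjusted p = 0.0081). For Ier5 they were instead 1.35 (adjusted p = 0.0051) and 0.40 (adjusted p = 0.59). For Mtmr1 they were -1.34 (adjusted p = 0.0090) and -0.34 (adjusted p = 0.69).

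Of the 22 glucocorticoid-responsive genes, 0 passed over all genes tested and 6 rose adjusted over the list alone in injured against sham raphe, and 20 were higher, with a mean of 0.25 and an adjusted p = 3.8e-04. The call was lost at an adjusted p = 0.128 with an estimated correlation, and with control covariates (mean 0.16, adjusted p = 0.083). Cdkn1a (0.63, adjusted p = 0.082, 18 of 24) and Klf9 (0.47, adjusted p = 0.083, 22 of 24) were the members with the smallest p. Of 25 meninges and fibroblast genes, 1 rose (2 over the list alone), with a mean of 0.20 and an adjusted p = 0.036. Their adjusted p was 0.403 with an estimated correlation, 0.145 without the doubted samples and 0.135 without raphe injured at 4 h, replicate 1, and the call was lost for 10 of 35 samples left out. The member that rose was Timp3, an inhibitor of matrix metalloproteinases (0.57, adjusted p = 0.0043, 21 of 24). The other 31 lists, serotonin and monoamine, growth and regeneration, astrocyte and microglia genes among them, had adjusted p from 0.129.

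In all 177 of 18716 raphe probe sets passed, 120 higher and 57 lower. When the doubted samples were left out, 875 passed, 514 higher and 361 lower, with 175 of the 177 among them, and 1158 passed without raphe injured at 4 h, replicate 1, alone. Leaving out raphe sham at 28 d, replicate 2, gave 77, the lowest count with any 1 sample left out. The labels give the source as raphe magnus for sham and naive samples and as raphe for injured samples, so a difference in dissection and the injury cannot be told apart by the design.

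**Figure D2:**
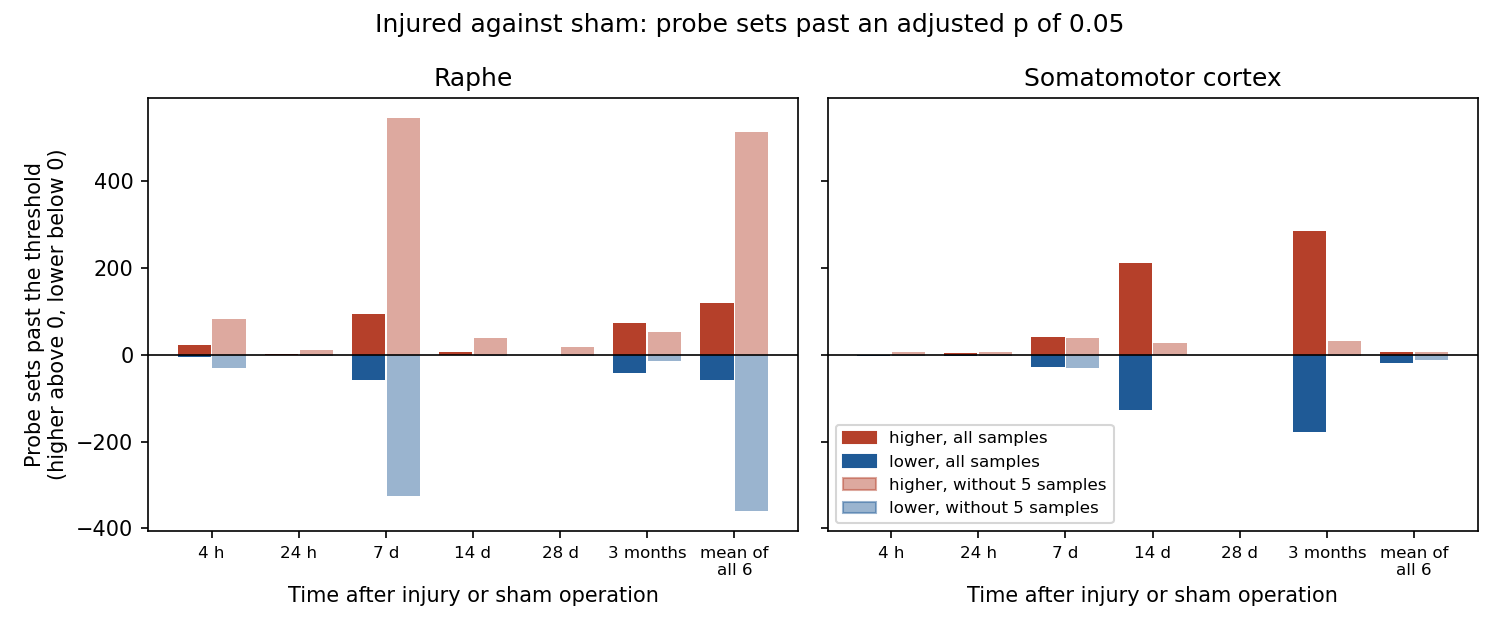
Number of probe sets past an adjusted p of 0.05 in injured against sham samples (vertical axis, higher above 0 and lower below 0) at each time and for the mean of all 6, with all samples (dark bars) and without the 5 doubted samples (light bars). In the raphe the mean of 6 times gave 120 higher and 57 lower with all samples, and 514 and 361 without the 5; in the cortex at 3 months 286 and 177 became 32 and 2.

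At each time, injured raphe was compared with the 2 sham samples of that time. At 4 h the growth factor gene Hbegf rose by 1.49 ± 0.28 (n = 4 and 2, adjusted p = 0.030), the transcription factor gene Yy1 by 1.28 ± 0.22 (adjusted p = 0.027), and Utp15, Dlgap4 and Fjx1 by 1.04 to 1.62. C12h7orf50 (-1.40 ± 0.27), Eif4ebp2 (-1.37 ± 0.29), a repressor of translation, Nup188 (-1.05 ± 0.22) and Mrpl41 (-1.03 ± 0.21) fell. All 4 injured samples lay on the side of the change for each of these 9 genes. The sham means of Utp15 and Hbegf lay below the negative controls. Utp15 did not pass without the doubted samples (adjusted p = 0.057), nor Fjx1 with a correction for place in identifier order (adjusted p = 0.065). Each of the 9 was lost with at least 1 single sample left out. In all 28 probe sets passed, 22 higher and 6 lower. After removal of the doubted samples, there were 114, 83 higher and 31 lower (25 of the 28 among them), and the share that was higher moved from 78.6 to 90 percent under quantile normalization. Leaving out raphe sham at 4 h, replicate 2, left 7, and leaving out raphe injured at 4 h, replicate 4, gave 116. None of the 33 lists passed at 4 h (adjusted p from 0.313).

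At 24 h Cyp4b1, a cytochrome P450 enzyme, was the 1 probe set past the threshold in the raphe, higher by 2.17 ± 0.37 (n = 4 and 2, adjusted p = 0.030, 4 of 4; lost for 3 of 6 samples left out, up to 0.213), with 816 at an unadjusted p under 0.05 in limma. Pla1a (1.63 ± 0.30, adjusted p = 0.054), Dpep2 (1.46, adjusted p = 0.054), Ccdc91 (2.15, adjusted p = 0.108), the chaperone gene Hspa5 (-0.84, adjusted p = 0.12) and Gpatch4 (1.25, adjusted p = 0.15) did not pass. Of 22 glucocorticoid-responsive genes 18 were higher, with a mean of 0.50 and an adjusted p = 2.0e-06, and 0 passed singly, also adjusted over the list alone. Fkbp5, a target gene of the glucocorticoid receptor, stood at 1.11 (adjusted p = 1.0). This list passed with an estimated correlation as well (adjusted p = 0.012) and with any 1 sample left out. Serotonin and monoamine genes were lower (15 of 18, 0 past singly, also over the list alone, mean -0.35, adjusted p = 0.012), at an adjusted p = 0.079 with an estimated correlation, and lost for 2 of 6 samples left out, with a mean of -0.17 (adjusted p = 0.599) without raphe sham at 24 h, replicate 2. Htr1a stood at -1.10, Th at -0.74 and the serotonin transporter gene Slc6a4 at -0.39, each lower in 4 of 4 samples. The 9 choroid plexus genes, a marker of neighbouring tissue, were lower too (0 past singly, mean -0.89, adjusted p = 0.037), at an adjusted p = 0.610 with an estimated correlation and 0.080 without the doubted samples. They were lost for 3 of 6 samples left out, with a mean of -0.17 (adjusted p = 0.921) without raphe sham at 24 h, replicate 1. The other 30 lists at 24 h had adjusted p from 0.157. Without the doubted samples 14 probe sets passed, 11 higher and 3 lower, and 28 without raphe sham at 24 h, replicate 2, while none passed without raphe injured at 24 h, replicate 3.

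At 7 d Ccn2 was higher in injured raphe by 2.83 ± 0.46 (n = 4 and 2, adjusted p = 0.0024, 4 of 4). Cryba2 rose by 2.73 ± 0.60, the kinase gene Akt2 by 2.58 ± 0.55, S100a11 by 2.32 ± 0.42 (adjusted p = 0.0048) and Hspa13 by 2.16 ± 0.39 (adjusted p = 0.0047). Ccn2 and all these but Akt2 had sham means below the negative controls. Abcd3, a peroxisomal transporter, fell by 2.17 ± 0.50, Zfp280b by 2.05, Ces1dl1 by 1.96, Mtmr1 by 1.94 and the cytokine gene Il12b by 1.84, each lower in 4 of 4 samples. Each of these 10 genes was lost with at least 1 sample left out. None of the 33 lists passed (adjusted p from 0.108). In all 150 probe sets passed, 93 higher and 57 lower. When the doubted samples were left out, there were 872, 546 higher and 326 lower (149 of the 150 among them). Each sample left out lowered the count, to 46 without sham replicate 2 and to at most 99.

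At 14 d Gad2, an enzyme of GABA synthesis, was higher by 1.97 ± 0.37 (n = 4 and 2, adjusted p = 0.029, 4 of 4) and Tox3 by 1.79 ± 0.27 (adjusted p = 0.0045, 4 of 4). Sec16b (-1.35, adjusted p = 0.051), Slc13a2 (-1.75, adjusted p = 0.103), Nufip2 (0.94, adjusted p = 0.133), Timp3 (1.03, adjusted p = 0.160) and Tbl1x (1.33, adjusted p = 0.160) did not pass. Glucocorticoid-responsive genes were higher on the mean (15 of 22, mean 0.41, adjusted p = 0.0067), as were choroid plexus genes (8 of 9, mean 1.33, adjusted p = 0.0047) and ribosomal proteins (48 of 66, mean 0.16, adjusted p = 0.019). With an estimated correlation the adjusted p was 0.242, 0.309 and 0.242, and no member of these lists passed singly, also adjusted over the list alone. They were lost for 2, 1 and 3 of 6 samples left out (adjusted p up to 0.061, 0.076 and 0.309), and Gad2 and Tox3 for 4 and 1 (up to 0.396 and 0.119). Ttr, the main choroid plexus transcript, stood at 4.77 (adjusted p = 0.605). The remaining 30 lists had adjusted p from 0.060. In all 7 probe sets passed, 7 higher, and 42 without the doubted samples, 38 higher and 4 lower, with the 7 among them. Without raphe sham at 14 d, replicate 2, 22 passed, and without raphe injured at 14 d, replicate 1, 4.

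At 28 d 0 raphe probe sets passed in limma, with 1273 at an unadjusted p under 0.05, and 249 passed with array quality weights. The smallest p belonged to Ptn, a heparin-binding growth factor (1.78 ± 0.34, n = 4 and 2, adjusted p = 0.073), Cand1 (1.47, adjusted p = 0.079), Vps37d (-0.83, adjusted p = 0.090), S100a11 (1.93, adjusted p = 0.137) and Lcmt2 (-2.29, adjusted p = 0.163), each with 4 of 4 samples on that side. On the mean, glucocorticoid-responsive genes were higher (18 of 22, mean 0.52, adjusted p = 7.1e-04), as were blood cell genes (7 of 8, 2 past over the list alone, mean 0.58, adjusted p = 0.0028) and meninges and fibroblast genes (16 of 25, mean 0.44, adjusted p = 0.0080). Mitochondrial respiratory chain genes were lower (17 of 77 higher, mean -0.21, adjusted p = 7.1e-04). Under an estimated correlation these adjusted p were 0.117, 0.312, 0.561 and 0.098, and they were lost for 1, 1, 2 and 1 of 6 samples left out (up to 0.081, 0.063, 0.287 and 0.104). Apart from the 2 blood cell genes no member passed, also over the list alone. Among the other 29 lists adjusted p began at 0.066. After removal of the doubted samples, 19 probe sets passed, 17 higher and 2 lower, and without raphe sham at 28 d, replicate 1, 28.

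At 3 months S100a11 was higher in injured raphe by 2.47 ± 0.42 (n = 4 and 2, adjusted p = 0.0088, 4 of 4). It was higher by 2.36 without the doubted samples, which left 1 sham sample at this time. Ints8 (2.08 ± 0.39) rose as well, also without them. Both were lost with raphe sham at 3 months, replicate 1, alone left out (adjusted p = 0.12 and 0.123). Cyp2j3 was higher by 2.18 ± 0.43 than 1 sham sample, not a doubted one, which was assumed to vary like the other groups. Urm1 (3.28 ± 0.73) and Dera (2.18 ± 0.37) rose, and Fam107a (-2.39 ± 0.57), Hpcal4 (-2.34 ± 0.54), Nptxr (-2.23 ± 0.44), Enc1 (-2.12 ± 0.47) and Mical2 (-1.91 ± 0.43) fell, but these 7 did not pass without the doubted samples. One of the 2 sham samples was the one labelled raphe sham at 3 months, replicate 1, with a region score of 0.0493. Forebrain cortex genes were lower in the injured samples (1 of 19 fell, Ngef at -1.85, 2 over the list alone; mean -0.46, adjusted p = 0.0055), and their mean was -0.08 (adjusted p = 0.530) without the doubted samples. Synaptic vesicle genes were lower (0 of 30 past singly, mean -0.26, adjusted p = 0.017). Mitochondrial respiratory chain genes were higher (61 of 77 higher, 2 past over the list alone, mean 0.32, adjusted p = 4.6e-04). All 3 lists passed with an estimated correlation (adjusted p = 0.021), and the other 30 lists had adjusted p from 0.082. The synaptic vesicle call was lost without raphe injured at 3 months, replicate 2 (adjusted p = 0.066), and the mitochondrial call was not lost with any 1 sample left out. In all 115 probe sets passed, 74 higher and 41 lower, 8 of them on type A with 1 sham sample, and 66 without the doubted samples, 52 higher and 14 lower, of which 22 were among the 115. Without raphe sham at 3 months, replicate 1, alone 17 passed, and the other samples left out singly gave at most 55.

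The limma F test of whether the injured minus sham difference changed over time in the raphe had 0 of 18716 probe sets past the threshold, with 1974 at an unadjusted p under 0.05, and 62 passed with array quality weights. The 5 genes with the smallest p were Psmb8, a subunit of the immunoproteasome (highest at 7 d with 1.90, lowest at 24 h with -0.59, adjusted p = 0.054), Eif4ebp2 (1.28 at 7 d, -1.37 at 4 h), Dpm3, Tox3 and S100a11 (2.47 at 3 months, -0.65 at 4 h, adjusted p = 0.056). When the doubted samples were left out, 75 passed, and 180 without raphe injured at 4 h, replicate 1.

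Among the injured raphe samples alone, the F test over time gave 91 probe sets. Pnpla2, a triglyceride lipase, was highest at 24 h (11.42) and lowest at 28 d (10.13, a range of 1.29, adjusted p = 6.0e-04, n = 4 at each time). Cyp4b1 (range 2.23), Gpatch4 (1.49), Gpd1 (1.39), a glycerol phosphate dehydrogenase, and Prkaca (1.56), a catalytic subunit of protein kinase A, were also highest at 24 h and were lowest at 3 months. Pla1a was highest at 24 h (range 1.66) and lowest at 7 d, and Grifin was highest at 4 h (range 1.94) and lowest at 3 months. Emcn, an endothelial sialomucin, and Gstm5 were highest at 3 months with ranges of 1.05 and 1.01, and Evc was highest at 28 d. When the doubted samples were left out, 814 passed, 89 of the 91 among them, with 697 without raphe injured at 4 h, replicate 1, and 37 without raphe injured at 3 months, replicate 4, where Prkaca was lost (adjusted p = 0.064).

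Injured against naive raphe mixed operation, injury and any age difference. Of 22 glucocorticoid-responsive genes 4 rose and 0 fell (7 and 1 over the list alone; mean 0.47, adjusted p = 2.0e-04). These were Klf9, a transcription factor (1.03, adjusted p = 0.0033, 24 of 24 samples), Arrdc2 (1.37, adjusted p = 0.0055, 24 of 24), Cdkn1a, a cell cycle inhibitor (1.00, adjusted p = 0.033, 20 of 24) and Bcl6 (0.97, adjusted p = 0.038, 24 of 24). Of 8 blood cell genes 3 fell, the haemoglobin genes Hba-a1 (-1.0), Hbb-b1 (-0.76) and Hbb (-0.70), and 1 rose and 6 fell over the list alone (mean -0.61, adjusted p = 6.7e-05). Of 66 ribosomal proteins 2 rose and 2 fell (4 and 11 over the list alone; mean -0.11, adjusted p = 0.0039). With an estimated correlation the adjusted p of these lists was 0.071, 0.071 and 0.072. Without raphe naive, replicate 3, the ribosomal mean was -0.07 (adjusted p = 0.0499). The other 30 lists had adjusted p from 0.062. In all 570 probe sets passed, 416 higher and 154 lower (n = 24 and 4). After removal of the doubted samples, there were 2081, 1305 higher and 776 lower, with all 570 among them; leaving out raphe injured at 4 h, replicate 1, gave 1893 and leaving out raphe naive, replicate 2, gave 316.

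Sham against naive raphe mixed the operation with any age difference. Ipo9, an importin, was higher in sham raphe by 2.28 ± 0.25 (n = 12 and 4, adjusted p = 4.6e-06, 12 of 12). The adhesion molecule gene Selp (1.98 ± 0.28), COX2 (1.96 ± 0.44), Commd10 (1.74 ± 0.31) and Atad2 (1.66 ± 0.40) rose, each in every sham sample measured. Pf4, a platelet chemokine (-2.02 ± 0.44), Ube2g2 (-1.89 ± 0.39), Nell2 (-1.81 ± 0.36), Scd2, a stearoyl-CoA desaturase (-1.70 ± 0.34), and Pla2g2a (-1.52 ± 0.28) fell, in all sham samples or, for Pla2g2a, in 10 of 11. Of 8 blood cell genes 6 fell (1 rose and 6 fell over the list alone; mean -0.74, adjusted p = 1.7e-06, 0.033 with an estimated correlation), and of 18 apoptosis genes 1 rose, Bid at 1.02 (1 over the list alone; mean 0.24, adjusted p = 0.028, 0.033 with an estimated correlation). Microglia and macrophage genes (1 of 26 fell, Cd63 at -0.53; 1 over the list alone; mean -0.18, adjusted p = 0.027), meninges and fibroblast genes (1 of 25 rose, Sparc at 1.16; 1 rose and 6 fell over the list alone; mean -0.34, adjusted p = 0.025) and ribosomal proteins (1 of 66 rose and 1 fell; 1 and 5 over the list alone; mean -0.12, adjusted p = 0.0027) were lower on the mean. Their adjusted p was 0.059, 0.304 and 0.059 with an estimated correlation. The apoptosis and meninges calls were lost without the doubted samples (adjusted p = 0.067 and 0.058) and, like the microglia call, with at least 1 single sample left out (adjusted p up to 0.072, 0.068 and 0.067). COX2, Atad2 and Pf4 were lost in that way too (adjusted p up to 0.102, 0.153 and 0.062). The other 28 raphe lists had adjusted p from 0.053. In all 253 probe sets passed, 157 higher and 96 lower, and 1132 without the doubted samples (640 higher and 492 lower, 252 of the 253 among them). A correction for place in identifier order gave 164 and lost Atad2 (adjusted p = 0.138), and leaving out raphe naive, replicate 2, gave 146.

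Injured against sham cortex over the 6 times tested the region of the corticospinal neurons. Sfpq, an RNA-binding splicing factor, fell by 0.54 ± 0.07 (n = 24 and 12, adjusted p = 2.3e-04, 20 of 24 injured samples). Aif1, a marker of microglia and macrophages, was higher by 0.63 ± 0.10 (adjusted p = 0.0058, 19 of 24), and the kinase gene Hunk by 0.41 ± 0.07 (adjusted p = 0.0058, 21 of 24). Exoc8, a subunit of the exocyst, fell by 0.56 ± 0.11 (adjusted p = 0.026, 18 of 24), and Slc52a3, a riboflavin transporter, by 0.41 ± 0.09 (adjusted p = 0.040, 20 of 24). Hunk (adjusted p = 0.060) and Slc52a3 (adjusted p = 0.132) did not pass without the doubted samples, nor Slc52a3 with a correction for place in identifier order (adjusted p = 0.088). With 1 sample left out, Exoc8 (3 of 36) and Slc52a3 (19 of 36) were lost. Aif1 and Exoc8 differed most at 7 d (2.79 and -2.18), where sham Aif1 was near background. Against naive cortex Aif1 stood at -0.87 in sham (adjusted p = 0.020) and -0.24 in injured samples (adjusted p = 0.46). For Sfpq these were -0.01 (adjusted p = 0.98) and -0.56 (adjusted p = 0.0085).

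Forebrain cortex genes were higher on the mean (22 of 25, 0 past singly, also over the list alone, mean 0.14, adjusted p = 0.012) and brainstem genes lower (1 of 11 higher, 0 past singly, also over the list alone, mean -0.23, adjusted p = 0.012). Under an estimated correlation the adjusted p was 0.781 and 0.076, and without the doubted samples 0.907 and 0.233. They were lost for 4 and 1 of 36 samples left out, with means of 0.01 and -0.17 without cortex sham at 3 months, replicate 1 (adjusted p = 0.985 and 0.086). The other 31 lists had adjusted p from 0.182. In all 25 of 18769 probe sets passed, 7 higher and 18 lower. With control covariates 1 passed, Sfpq, and with array quality weights 5, without Exoc8 and Slc52a3. When the doubted samples were left out, there were 18, 6 higher and 12 lower, of which 9 were among the 25. Single samples moved this count from 9 (without cortex injured at 7 d, replicate 4) to 653 (without cortex sham at 14 d, replicate 1).

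**Figure D3:**
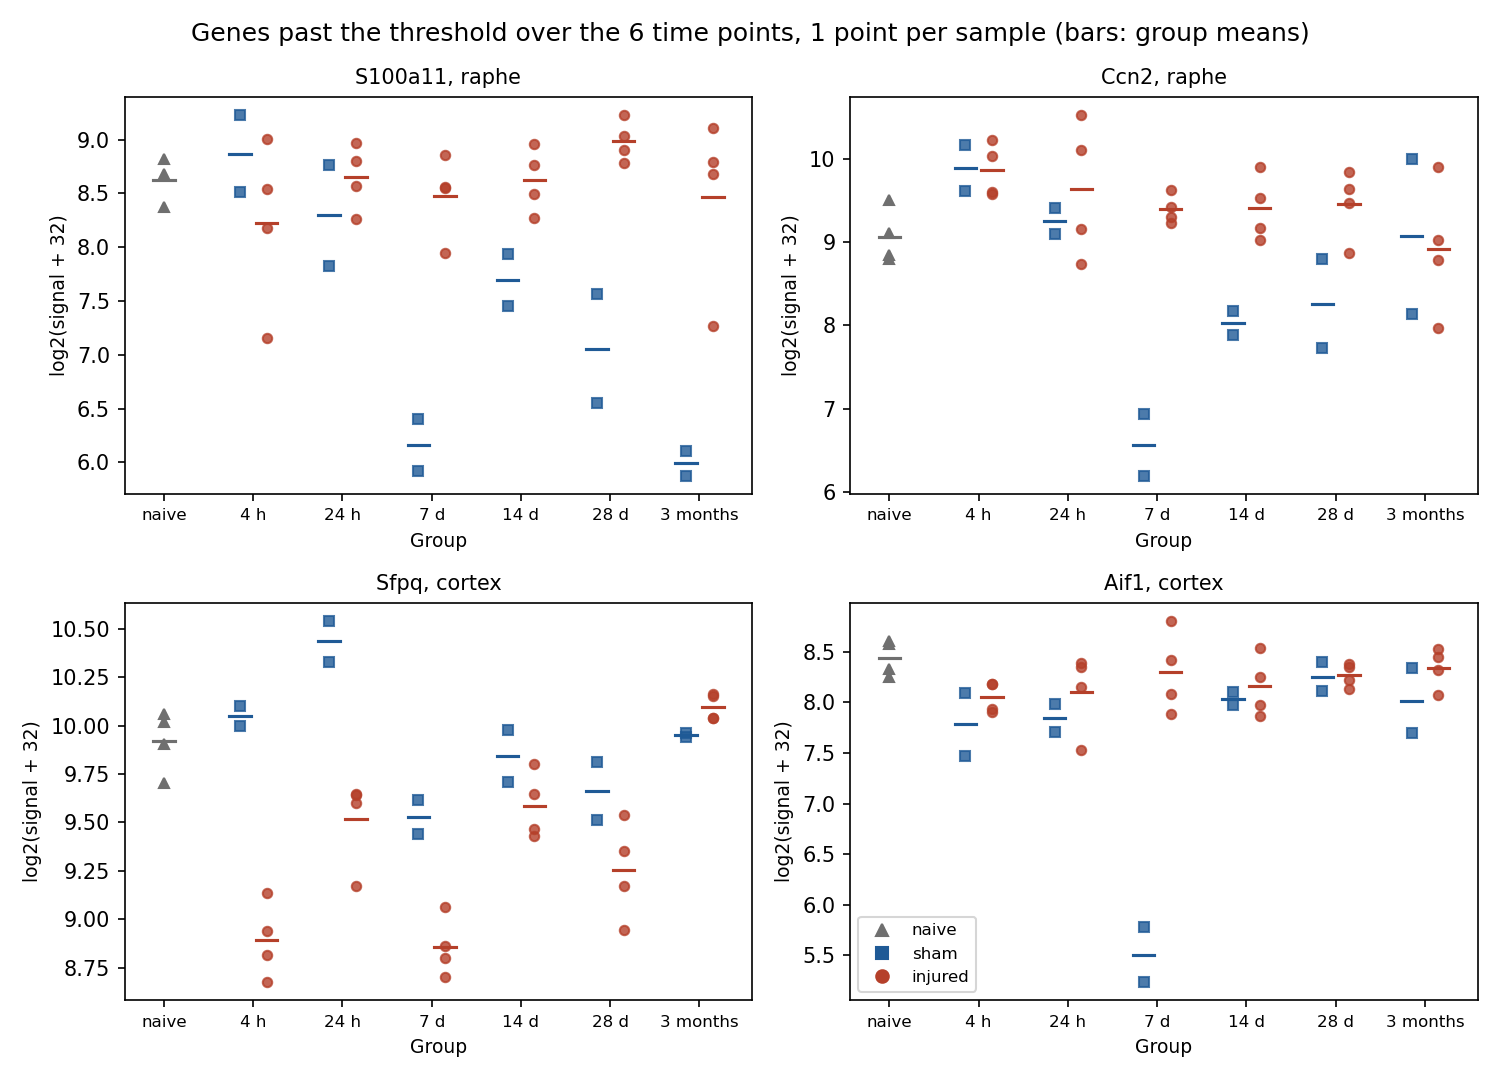
Expression (vertical axis, log2 of the signal with 32 added) of S100a11 and Ccn2 in the raphe and of Sfpq and Aif1 in the cortex, 1 point per sample, with bars at group means. Injured samples of Sfpq at 4 h have a mean of 8.89 against 10.05 in sham samples.

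At 4 h Sfpq fell in injured cortex by 1.15 ± 0.17 (n = 4 and 2, adjusted p = 0.0039, 4 of 4). It was the 1 named gene among 3 probe sets past the threshold, all lower, with 1485 at an unadjusted p under 0.05 in limma, and was lost without cortex sham at 4 h, replicate 1 (adjusted p = 0.080). Bmp4 (1.80 ± 0.36, adjusted p = 0.091), Dnaaf5 (1.10, adjusted p = 0.091), Pprc1 (2.09, adjusted p = 0.091), Cmas (1.91, adjusted p = 0.101) and Slc3a2 (0.89, adjusted p = 0.108) did not pass. Ribosomal proteins were lower on the mean (17 of 66 higher, 0 past singly and 3 lower over the list alone, mean -0.22, adjusted p = 1.9e-06). Meninges and fibroblast genes were higher on the mean (17 of 25, 0 past singly, also over the list alone, mean 0.21, adjusted p = 0.047). Of these 2 the meninges call was lost for 3 of 6 samples left out (adjusted p up to 0.478). With an estimated correlation the adjusted p was 0.495 and 0.420, and the other 31 lists had adjusted p from 0.091. After removal of the doubted samples, 10 probe sets passed, 6 higher and 4 lower, and without cortex sham at 4 h, replicate 2, 13, while 1 passed without cortex injured at 4 h, replicate 1.

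At 24 h Ikbkb, a kinase that activates NF-kappaB, was higher by 1.33 ± 0.26 (n = 4 and 2, adjusted p = 0.039, 4 of 4) and Sfpq lower by -0.92 ± 0.17 (adjusted p = 0.039, 4 of 4). They were lost for 5 and 6 of 6 samples left out singly (adjusted p up to 0.484 and 0.420), and Sfpq with a correction for place in identifier order (adjusted p = 0.072). Brd7 (0.62, adjusted p = 0.082), ST7 (1.64, adjusted p = 0.082), Tmem86a (1.12, adjusted p = 0.105), the glycosyltransferase gene Lfng (-1.73, adjusted p = 0.155) and Tasor2 (1.37, adjusted p = 0.163) did not pass. On the mean, immediate early genes were lower (9 of 26 higher, mean -0.26, adjusted p = 0.0060), as were ribosomal proteins (12 of 66 higher, mean -0.23, adjusted p = 2.5e-05) and mitochondrial genes (26 of 78 higher, mean -0.18, adjusted p = 0.0055), and myelin genes were higher (18 of 22, mean 0.20, adjusted p = 0.0497). The immediate early, mitochondrial and myelin calls were lost for 2, 2 and 5 of 6 samples left out (adjusted p up to 0.353, 0.131 and 0.353). All 4 had an adjusted p of 0.638 with an estimated correlation and no member past singly, also adjusted over the list alone. The other 29 lists had adjusted p from 0.119. In all 8 probe sets passed, 4 higher and 4 lower, and 11 without the doubted samples, 7 higher and 4 lower, with the 8 among them. The share that was higher moved from 50 to 60 percent under quantile normalization. Without cortex sham at 24 h, replicate 1, 32 passed, and without cortex injured at 24 h, replicate 2, 2.

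At 7 d Aif1 was higher in injured cortex by 2.79 ± 0.25 (n = 4 and 2, adjusted p = 2.5e-08, 4 of 4), with means of 8.30 in injured, 5.51 in sham and 8.44 in naive samples. That sham mean lay below that of the negative control probe sets on the same arrays (6.75). The size of this difference, like those for Ptgs2, Gnal and Hoxd9 below, rests on signal near background. Ptgs2, the inducible cyclooxygenase, rose by 2.27 ± 0.39 (adjusted p = 0.0041), the G protein gene Gnal by 2.21 ± 0.43, Hoxd9 by 2.09 ± 0.46 and Cmtm8 by 1.82 ± 0.38. Exoc8 fell by 2.18 ± 0.26 (adjusted p = 1.8e-05), Tmco6 by 2.08 ± 0.47, Rpl23a by 1.94 ± 0.35, Kpna1, an importin, by 1.48 ± 0.30 and Chchd1 by 1.00 ± 0.21, each in 4 of 4 samples. Of these 10 genes Tmco6 did not pass without the doubted samples (adjusted p = 0.067) or with a correction for place in identifier order (adjusted p = 0.060). All but Aif1 and Exoc8 were lost with at least 1 single sample left out. None of the 33 lists passed (adjusted p from 0.387). In all 69 probe sets passed, 41 higher and 28 lower, and 69 without the doubted samples, 38 higher and 31 lower, of which 47 were shared. Without cortex injured at 7 d, replicate 4, 27 passed, and without cortex sham at 7 d, replicate 2, 110.

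At 14 d Nrep, a gene of neuronal regeneration, was higher in injured cortex by 3.26 ± 0.34 (n = 4 and 2, adjusted p = 4.8e-07, 4 of 4), and by 2.15 (adjusted p = 2.7e-04) without the doubted samples. Kbtbd4 (2.94 ± 0.37) and the ryanodine receptor gene Ryr2 (2.92 ± 0.38) rose in both cases, with 2.63 and 2.40 without the doubted samples. Leprotl1 (3.13 ± 0.42) and Skp1 (2.89 ± 0.76) rose, and Acp3 (-2.31 ± 0.62), Erbb2 (-1.94 ± 0.42), a receptor tyrosine kinase, Dll3 (-1.87 ± 0.49), Fbxl17l1 (-1.76 ± 0.37) and Hist4h4 (-1.76 ± 0.43) fell, but these 7 did not pass without the doubted samples, where Skp1 stood at -0.31. A correction for place in identifier order lost Skp1, Acp3, Dll3 and Hist4h4 (adjusted p = 0.058, 0.069, 0.054 and 0.059). Of the 10, Nrep, Leprotl1, Kbtbd4 and Ryr2 passed with any 1 sample left out. One of the 2 sham samples, replicate 2, had a 5th percentile of signal of 55.3. Ribosomal proteins were higher on the mean (55 of 66, 0 past singly, 12 higher and 1 lower over the list alone, mean 0.32, adjusted p = 1.3e-06), as were mitochondrial genes (2 of 78 rose, Uqcrq at 1.52 and Cox6c at 1.31, 3 over the list alone, mean 0.25, adjusted p = 1.7e-04) and proteasome genes (29 of 36, 0 past singly, also over the list alone, mean 0.17, adjusted p = 0.016). Immediate early genes were lower (5 of 26 higher, 0 past singly and 1 over the list alone, mean -0.40, adjusted p = 0.039). Under an estimated correlation the adjusted p was 0.431, 0.431, 0.431 and 0.436. Without the doubted samples the mitochondrial (adjusted p = 0.074) and proteasome (adjusted p = 0.322) calls were lost. The immediate early call was lost for 3 of 6 samples left out (adjusted p up to 0.343), and the ribosomal mean was 0.20 without cortex sham at 14 d, replicate 2 (adjusted p = 0.0013). The other 29 lists at 14 d had adjusted p from 0.059.

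In all 339 probe sets passed in the cortex at 14 d, 212 higher and 127 lower, 193 of them on array type C. When the doubted samples were left out, 28 passed, 27 higher and 1 lower, of which 24 were among the 339, and 6 passed with array quality weights. The share that was higher moved from 62.5 to 79.2 percent under quantile normalization. Without cortex sham at 14 d, replicate 2, 31 passed, and without replicate 1 of these 2, 3499.

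At 28 d 0 cortex probe sets passed in limma, with 597 at an unadjusted p under 0.05, and 0 without the doubted samples. The smallest p belonged to C1h19orf81 (1.28 ± 0.28, n = 4 and 2, adjusted p = 0.665), the ceramidase gene Acer2 (1.04, adjusted p = 0.807), C5h1orf159 (1.26), Bzw2 (0.89) and Bnip1 (0.76, adjusted p = 1.0), each higher in 4 of 4 samples. Glucocorticoid-responsive genes were higher on the mean (14 of 19, 0 past singly and 1 over the list alone, mean 0.23, adjusted p = 0.0096), with Sgk1 at 0.98, and passed with an estimated correlation (adjusted p = 0.012), but was lost for 2 of 6 samples left out (adjusted p up to 0.308). Brainstem genes were lower (2 of 11 higher, 0 past singly, also over the list alone, mean -0.40, adjusted p = 0.0097). Blood cell genes were higher (7 of 8, 0 past singly, also over the list alone, mean 0.38, adjusted p = 0.0097). With an estimated correlation the adjusted p of these 2 lists was 0.067 and 0.277, and each was lost for 3 of 6 samples left out (up to 0.308). The other 30 lists had adjusted p from 0.065. Without cortex sham at 28 d, replicate 2, 48 probe sets passed.

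At 3 months Man1a2, a mannosidase, was higher in injured cortex by 2.52 ± 0.37 (n = 4 and 2, adjusted p = 7.1e-04, 4 of 4) and by 1.88 without the doubted samples (adjusted p = 0.035). With cortex sham at 3 months, replicate 1, alone left out its adjusted p was 0.109. Cryba2 (2.63 ± 0.51), Klrb1a (2.35 ± 0.45), Stk35 (2.19 ± 0.42) and Ccn2 (2.16 ± 0.46) rose, and Tppp3 (-2.85 ± 0.64), Arl2 (-2.55 ± 0.43), Mfhas1 (-2.29 ± 0.44), Zfp276 (-2.25 ± 0.49) and Prph (-1.82 ± 0.47) fell, but these 9 did not pass without the doubted samples, and all 10 were lost without that 1 sham sample. One of the 2 sham samples was the one labelled cortex sham at 3 months, replicate 1, with a region score of 0.654. Of 22 myelin and oligodendrocyte genes 0 rose and 5 fell (15 over the list alone; mean -0.73, adjusted p = 1.7e-12, 0.049 with an estimated correlation), and without that sham sample the mean was -0.19 (adjusted p = 0.388). Of 25 neuronal cytoskeleton genes 3 fell, Nefl (-1.29), Nefh (-1.69) and Prph (7 over the list alone; mean -0.33, adjusted p = 5.9e-04, 0.049 with an estimated correlation). Forebrain cortex genes (3 of 25 rose, 7 over the list alone; mean 0.66, adjusted p = 9.0e-07), immediate early genes (3 of 26 rose, 4 over the list alone; mean 0.63, adjusted p = 1.2e-04) and voltage-gated ion channels (3 of 38 rose, 7 over the list alone; mean 0.45, adjusted p = 5.9e-04) were higher. Their adjusted p was 0.181, 0.181 and 0.057 with an estimated correlation.

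Lower on the mean in injured cortex at 3 months were also brainstem genes (2 of 11 fell, Nefh and Prph; mean -0.50, adjusted p = 0.038), proteasome genes (1 of 36 fell, Psmd2 at -0.49; mean -0.22, adjusted p = 5.9e-04), glycolysis genes (1 of 18 fell, Pkm at -0.65; mean -0.19, adjusted p = 0.044) and cholesterol synthesis genes (0 of 24 fell; mean -0.19, adjusted p = 0.044). Adjusted over the list alone, 2, 3, 2 and 2 of their members fell. Under an estimated correlation the adjusted p was 0.181, 0.181, 0.20 and 0.20. None of the 9 lists passed without the doubted samples (adjusted p from 0.426) or with cortex sham at 3 months, replicate 1, alone left out (adjusted p from 0.388), and the other 24 lists had adjusted p from 0.160 with all samples. In all 463 probe sets passed, 286 higher and 177 lower. After removal of the doubted samples, there were 34, 32 higher and 2 lower, of which 24 were among the 463. The share that was higher moved from 61.8 to 50.6 percent under quantile normalization. Without cortex sham at 3 months, replicate 1, 22 passed, and without replicate 2 of these 2, 1591.

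Whether the injured minus sham difference changed over time in the cortex was asked with the limma F test. Aif1 changed most clearly (2.79 at 7 d and 0.02 at 28 d, adjusted p = 5.9e-05, n = 4 and 2 at each time). Nrep (3.26 at 14 d, -0.30 at 28 d, adjusted p = 2.7e-04), Leprotl1, Hps4, Lmo7, Kbtbd4, Rbm15 and Ryr2 were highest at 14 d, with ranges of 2.39 to 3.82 between times. Exoc8 was lowest at 7 d (-2.18) and Ppp1ca, a catalytic subunit of protein phosphatase 1, highest at 7 d (1.13). Leprotl1, Kbtbd4, Rbm15 and Ryr2 did not pass without the doubted samples. A correction for place in identifier order lost Nrep, Hps4, Rbm15 and Ryr2 (adjusted p = 0.051, 0.096, 0.096 and 0.088), and leaving out cortex sham at 14 d, replicate 2, lost Leprotl1 too (adjusted p = 0.058). In all 182 probe sets passed, and 31 without the doubted samples, of which 20 were among the 182. Without cortex sham at 14 d, replicate 1, 2171 passed, and without cortex sham at 3 months, replicate 1, 53.

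Among the injured cortex samples alone, expression over time differed for 206 probe sets. Fkbp5 was highest at 4 h (10.45) and lowest at 3 months (7.96, a range of 2.50, adjusted p = 4.7e-04, n = 4 at each time). Tsc22d3, another target gene of the glucocorticoid receptor (range 1.13), Sesn1, a stress-induced gene (range 1.84), and Gpatch4 (range 1.53) were also highest at 4 h and lowest at 3 months. Mrpl41, a mitochondrial ribosomal protein, was highest at 4 h and lowest at 28 d (range 1.78, adjusted p = 1.2e-06), as was Fam43a (range 1.08). Fn1, fibronectin (range 1.13), Gpd1 (range 1.45) and Acer2 (range 1.36) were highest at 24 h. Sfpq was lowest at 7 d (8.86) and highest at 3 months (10.10, adjusted p = 1.2e-05). Without the doubted samples 407 passed, with 201 of the 206 among them. Without cortex injured at 3 months, replicate 1, 86 passed.

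Injured against naive cortex mixed operation, injury and any age difference. Of 19 glucocorticoid-responsive genes 4 rose and 1 fell (11 and 1 over the list alone; mean 0.37, adjusted p = 1.0e-04, 3.0e-04 with an estimated correlation). Sgk1 rose by 0.91 (adjusted p = 0.0053, 22 of 24 samples), Klf9 by 0.60 (adjusted p = 0.024, 21 of 24) and Tsc22d3 by 0.56 (adjusted p = 0.014, 21 of 24), while Glul, the glutamine synthetase of astrocytes, fell by 0.61 (adjusted p = 0.011, 24 of 24). Of 66 ribosomal proteins 0 rose and 7 fell (21 over the list alone; mean -0.23, adjusted p = 1.2e-10). Of 22 astrocyte genes 2 fell, Glul and the lipoprotein gene Apoe (-0.53), and over the list alone 1 rose and 3 fell (mean -0.14, adjusted p = 0.016). Myelin genes were lower (0 of 22 past singly, 2 over the list alone, mean -0.19, adjusted p = 0.0059). Immediate early genes were higher (22 of 26, 0 past singly, 1 over the list alone, mean 0.24, adjusted p = 0.016). With an estimated correlation the adjusted p of these last 4 lists was 0.090, 0.159, 0.535 and 0.535. The astrocyte, myelin and immediate early calls were lost with some naive samples left out (adjusted p up to 0.093, 0.074 and 0.416). The other 28 lists had adjusted p from 0.079. In all 375 probe sets passed, 197 higher and 178 lower (n = 24 and 4), and 754 without the doubted samples (428 higher and 326 lower, 374 of the 375 among them). Without cortex naive, replicate 2, 66 passed.

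Sham against naive cortex mixed the operation with any age difference. Ceacam12 was higher in sham cortex by 2.01 ± 0.40 (n = 12 and 4, adjusted p = 0.023, 12 of 12), Bmp7, a growth factor, by 1.58 ± 0.29 (11 of 12), Smarca5, a chromatin remodeller, by 1.43 ± 0.25, Ubr1 by 1.34 and Prm3 by 1.24. Nrl (-1.48 ± 0.33), Cyba, a subunit of the phagocyte oxidase (-1.27 ± 0.30), Aif1 (-0.87 ± 0.17, adjusted p = 0.020, 12 of 12), Dnaaf9 (-0.83) and Cd99 (-0.71) fell. Prm3 did not pass without the doubted samples (adjusted p = 0.069). A correction for place in identifier order lost Ubr1, Prm3 and Cd99 (adjusted p = 0.054, 0.070 and 0.089). With 1 sample left out, all of these 10 genes but Bmp7 were lost at least once, Dnaaf9 for 14 and Cyba for 13 of 16 samples. Of 25 microglia and macrophage genes 1 fell, Aif1 (1 over the list alone; mean -0.17, adjusted p = 0.0069), and of 19 glucocorticoid-responsive genes 1 rose, Tsc22d3 at 0.73, and 1 fell, Glul at -0.62 (3 and 1 over the list alone; mean 0.27, adjusted p = 0.0069). Both lists passed with an estimated correlation (adjusted p = 0.024). Immediate early genes were higher (22 of 26, 0 past singly, 1 over the list alone, mean 0.28, adjusted p = 0.0027), as were brainstem genes (9 of 11, 0 past singly, 1 over the list alone, mean 0.36, adjusted p = 0.037). Astrocyte genes (1 of 22 fell, 1 over the list alone, mean -0.13, adjusted p = 0.043), myelin genes (0 of 22 past singly, also over the list alone, mean -0.17, adjusted p = 0.022) and ribosomal proteins (3 of 66 fell, 14 over the list alone, mean -0.21, adjusted p = 1.2e-09) were lower. Under an estimated correlation the adjusted p of these 5 lists was 0.420, 0.159, 0.230, 0.627 and 0.090. The brainstem call was lost without the doubted samples (adjusted p = 0.082). With 1 sample left out the immediate early, brainstem, astrocyte and myelin calls were lost at least once (adjusted p up to 0.161, 0.110, 0.248 and 0.344). Among the other 26 lists adjusted p began at 0.358. In all 92 probe sets passed, 45 higher and 47 lower, and 157 without the doubted samples, 94 higher and 63 lower, of which 70 were among the 92. Without cortex naive, replicate 2, 18 passed, and without cortex sham at 14 d, replicate 1, 318.

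**Figure D4:**
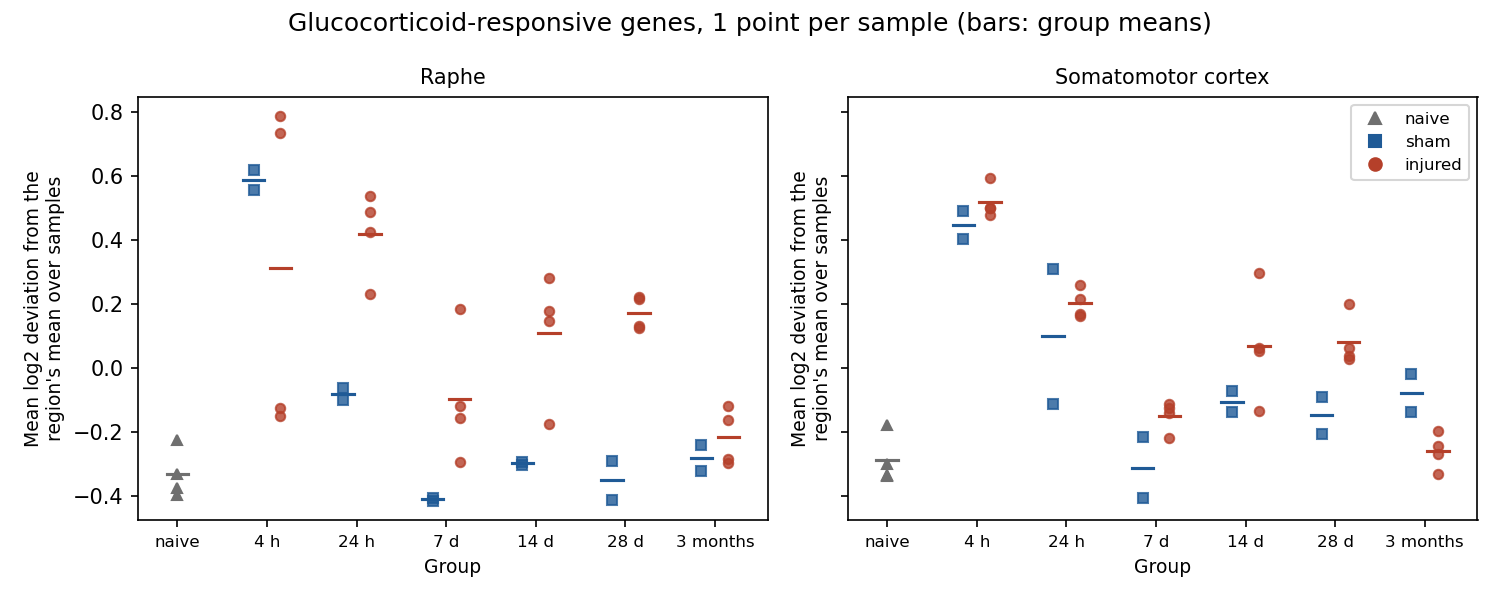
Mean of the glucocorticoid-responsive genes in each sample (vertical axis, log2 deviation from the mean over all samples of the region), 1 point per sample, with bars at group means, by treatment and time. In both regions the 2 sham samples at 4 h lie above the sham samples of the other times.

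Raphe minus cortex of the injured minus sham difference tested whether the regions differed in the injury effect over the 6 times. Hist4h4 differed by 1.09 ± 0.22, with 0.74 in the raphe and -0.35 in the cortex (n = 35 and 36 samples, adjusted p = 0.046). Hoxc4, a homeobox gene, differed by 1.37 ± 0.28, with 0.56 and -0.81 (adjusted p = 0.046), and Hunk by -0.49 ± 0.10, with -0.07 and 0.41 (adjusted p = 0.046). A correction for place in identifier order lost all 3 (adjusted p = 0.121, 0.055 and 0.121), and so did 51, 58 and 52 of the 71 samples left out singly. Eva1b (1.36, adjusted p = 0.096), Lysmd2 (0.73), Tfg (0.58), Lamc1 (-0.59) and Dlgap1 (-0.66) did not pass. On the mean, the effect in raphe was above that in cortex for interferon and MHC genes (22 of 29, mean 0.17, adjusted p = 0.0099), glucocorticoid-responsive genes (17 of 22, mean 0.19, adjusted p = 0.023), brainstem genes (13 of 19, mean 0.25, adjusted p = 0.0099) and meninges and fibroblast genes (19 of 25, mean 0.17, adjusted p = 0.032), and below it for forebrain cortex genes (5 of 25 above, mean -0.18, adjusted p = 0.018). No member passed over all genes tested, and 1 glucocorticoid-responsive gene passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.059, 0.214, 0.214, 0.525 and 0.439. None of the 5 lists passed without the doubted samples (adjusted p from 0.25), and the other 28 had adjusted p from 0.136 with all samples. Over all comparisons 78 of 660 list tests passed, 20 of them also with an estimated correlation and 54 without the doubted samples. In every fit that could be run with 1 sample left out, 31 passed. In all 4 of 19453 probe sets passed, 3 higher and 1 lower, with 1651 at an unadjusted p under 0.05 in limma. When the doubted samples were left out, 3 others passed, none passed with quantile normalization, and without cortex sham at 14 d, replicate 1, 64 passed.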

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

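The tests of this part were chosen only after the result was seen, except for the comparisons and the leaving out of single samples, which were fixed before.

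A Dixon test set 16 of 240 groups apart, where chance alone gives about 5 percent of groups. By the 5th percentile of signal it set apart cortex injured at 7 d, replicate 2, with 32.14 (next 14.14), and raphe injured at 3 months, replicate 3, with 16.39. By the actin 3' over 5' ratio it set apart raphe injured at 4 h, replicate 1, with 50.04 (next 2.592), cortex injured at 28 d, replicate 2, with 2.14, cortex injured at 3 months, replicate 1, with 1.501, and raphe naive, replicate 3, with 2.101. By log2 signal it set apart, in injured raphe, Letm2 at 3 months, replicate 1 (7.82), Mtmr1 at 24 h, replicate 3 (8.587), Lcmt2 at 3 months, replicate 3 (6.997), Ap5s1 at 4 h, replicate 2 (7.295), Suv39h2 at 28 d, replicate 1 (8.216) and Plau at 14 d, replicate 2 (6.887). In the cortex it set apart Hunk in injured at 3 months, replicate 4 (9.179), Exoc8 in injured at 28 d, replicate 1 (7.187) and in naive, replicate 1 (8.243), and Sfpq in injured at 24 h, replicate 1 (9.172).

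The injury effect differed between regions for 4 probe sets, and over time in the cortex for 182. Raphe minus cortex of this effect was 0.166 for interferon and MHC, 0.1933 for glucocorticoid-responsive and 0.2468 for brainstem genes. It was -0.178 for forebrain cortex and 0.1737 for meninges and fibroblast genes. None of the 5 passed with an estimated correlation or without the doubted samples. Among samples outside the comparisons, cortex sham at 30 min, replicate 2, had 1.136 for striatum genes and 0.8519 for choroid plexus genes. On the same 8 and 6 genes of type A the naive samples had at most 0.437 and 0.214, and the samples of the 6 times at most 0.284 and 0.396.

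In the cortex at 14 d 339 probe sets passed, and 3 explanations were tested. Signal tied to the place of probe sets in identifier order may account for part, since 34 neighbouring pairs passed in 1 direction, against a mean of 5.65 and a highest of 12 in 200 shuffles. This was not confined to that time, as injured against naive raphe had 49 such pairs (highest shuffle 25), sham against naive raphe 20 (7), the raphe at 7 d 4 (2) and sham against naive cortex 4 (2). The 339 were chosen on the 2 sham samples, so the displacement from other sham samples (0.862 of the difference) decides nothing. Over all probe sets 1208 passed there, and 0 between injured samples at 14 d and other times. Replicate 2 alone had a raised 5th percentile (55.3). The 0 speaks against a change at 14 d alone, not one shared by other times.

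In the raphe over 6 times 177 probe sets passed, S100a11 among them, and brightness of the arrays and a degraded sample were tested as explanations. Of the 177, 151 passed beside control covariates, but 2742 did in all, so brightness was not excluded. For the glucocorticoid-responsive genes brightness could not be told from the injury, with a mean of 0.157 beside these covariates (adjusted p = 0.083). Degraded RNA in raphe injured at 4 h, replicate 1, was excluded, with 175 of the 177 kept without it (1158 passed). The source names differ between injured and sham raphe, and a difference in dissection could not be told: region scores overlapped (0.902 to 0.962 and 0.908 to 0.972, doubted samples aside), the brainstem, cerebellum and choroid plexus lists had adjusted p of 0.946, 0.233 and 0.911, and meninges genes 0.036.

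In the cortex at 3 months myelin genes were lower on the mean (-0.73, and -0.19 with an adjusted p = 0.388 without cortex sham at 3 months, replicate 1), and 3 explanations were tested. The sample labelled cortex sham at 3 months, replicate 1, may carry tissue of another region, as 16 of the 463 probe sets stayed without it and 390 without replicate 2. A score of 0.654 excluded only a swap of unmixed samples. The lowest raphe sample not doubted had 0.902, and raphe injured at 4 h, replicate 1, had 0.870. The sample labelled raphe sham at 3 months, replicate 1, had 0.0493, within the cortex range. A change of myelin genes in the injured samples could not be told, with -0.275 in injured samples at 3 months against other injured samples (adjusted p = 2.8e-04, 0.80 with an estimated correlation).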

How the results depend on the processing

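The tests of this part were chosen only after the result was seen, except for the alternatives fixed before the files were opened. The cause of a moved count was not tested. Of 685 counts 393 stayed and 292 moved; of 5562 gene values 4652 stayed, 765 were weaker, 143 stronger and 2 reversed; of 1539 list shifts 1306 stayed, 228 were weaker and 5 reversed.

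Skp1 in cortex injured against sham at 14 d reversed to -0.3067 without the doubted samples and without cortex sham at 14 d, replicate 2, and was 6.081 without replicate 1 of that group. The shift of a list is the mean z score of its genes less that of all other genes, and is no log2 change. Without the doubted samples the shift of the forebrain cortex genes reversed to -0.0368 in the cortex over 6 times, to -0.426 in the cortex at 3 months and to 0.0529 in the difference between regions. In the cortex at 3 months the shift reversed to -0.4173 for forebrain cortex genes and to 0.005429 for cholesterol synthesis genes without replicate 1 of cortex sham at 3 months, and was 3.43 and -1.34 without replicate 2.

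Quantile normalization gave 2 probe sets in the raphe at 24 h, 9 for its change over time and 139 for its time course, 552 in the cortex at 14 d, 50 for sham against naive cortex and 0 for the difference between regions. With no filter there were 14 in the raphe at 4 h, 2 at 24 h, 4 at 28 d and 4 for its change over time, and 12 in the cortex over 6 times, 5 at 4 h, 3 at 24 h, 308 at 3 months, 22 for sham against naive and 0 for the difference between regions. A stricter filter gave 0 in the raphe at 24 h, 6 at 28 d, 6 for its change and 143 for its time course, 274 for the change in the cortex and 0 for the difference between regions.

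A pseudocount of 1 gave 4 in the raphe at 24 h, 13 at 14 d, 6 at 28 d and 8 for its change, 5 in the cortex at 4 h and 1 for the difference between regions. The higher pseudocount gave 14 in the raphe at 4 h, 4 at 14 d, 5 for its change and 145 for its time course, and 5 in the cortex at 24 h. Adjustment within each array type gave 6 in the raphe at 24 h, 5 at 28 d and 13 for its change. The correction for neighbouring identifiers gave 2 in the raphe at 24 h, 3 at 28 d, 10 for its change and 164 for sham against naive, 145 in the cortex at 14 d and 0 for the difference between regions.

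Array quality weights gave, in the raphe, 1538 over 6 times, 155 at 4 h, 14 at 24 h, 1066 at 7 d, 18 at 14 d, 249 at 28 d, 41 at 3 months, 1689 for injured and 679 for sham against naive, 62 for the change and 1130 for the time course. In the cortex these weights gave 5 over 6 times, 175 at 4 h, 29 at 24 h, 6 at 14 d, 54 at 3 months, 1143 for injured and 55 for sham against naive, 28 for the change and 1534 for the time course, and 0 for the difference between regions.

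With the replicate block, which takes equal replicate numbers as paired, there were 39 in the raphe over 6 times, 0 at 4 h, 0 at 24 h, 78 at 7 d, 4 at 14 d, 71 at 3 months and 57 for its time course. With the replicate block the cortex had 4 at 24 h, 224 at 14 d and 17 for sham against naive, and the difference between regions 0. The replicate numbers did not pair the samples of different groups.

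Over 6 times, control covariates gave 2742 in the raphe and 1 in the cortex, the highest signal as covariate 800 and 13, naive in place of sham 570 and 375, and leaving out 3 of the doubted samples 1158 and 11. Of the 78 gene lists an estimated correlation left 20, and with single samples left out 31 always passed and 47 did not.

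Without the doubted samples the raphe had 875 over 6 times, 114 at 4 h, 14 at 24 h, 872 at 7 d, 42 at 14 d, 19 at 28 d, 66 at 3 months, 2081 for injured and 1132 for sham against naive, 75 for the change and 814 for the time course. The cortex had 10 at 4 h, 28 at 14 d, 34 at 3 months, 754 for injured and 157 for sham against naive, 31 for the change and 407 for the time course.

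With 1 sample left out, the lowest and highest counts in the raphe were 77 and 1158 over 6 times, 7 and 116 at 4 h, 0 and 28 at 24 h, 46 and 99 at 7 d, 4 and 22 at 14 d, 0 and 28 at 28 d, 17 and 55 at 3 months, 316 and 1893 for injured and 146 and 249 for sham against naive, 0 and 180 for the change, and 37 and 697 for the time course. In the cortex they were 9 and 653 over 6 times, 1 and 13 at 4 h, 2 and 32 at 24 h, 27 and 110 at 7 d, 31 and 3499 at 14 d, 0 and 48 at 28 d, 22 and 1591 at 3 months, 66 and 551 for injured and 18 and 318 for sham against naive, 53 and 2171 for the change, and 86 and 248 for the time course. For the difference between regions they were 0 and 64, and for the naive regions 2254 and 2455.

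The fit without raphe sham at 3 months, replicate 2, could not be run, since no sham array of type A was left at that time. Where 1 sham sample remained, it was assumed to vary like the other groups. Of 110 named calls between groups 31, S100a11 at 7 d and 3 months among them, had a group mean below the negative controls. The sizes of these 31 differences rest on signal near background.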

Other observations

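The tests of this part were chosen only after the result was seen, except for the 12 split tests and the count of 1893, which were planned before.

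Sham samples at 4 h had more of the glucocorticoid-responsive genes than sham samples of the other 5 times. In the raphe the mean of 22 genes was higher by 0.864 (adjusted p = 2.0e-13, 8.9e-06 with an estimated correlation), and 1 rose, or 8 over the list alone. In the cortex the mean of 19 genes was higher by 0.555 (adjusted p = 5.7e-09, 1.2e-08 with an estimated correlation), and 1 rose, or 6 over the list alone. Fkbp5, a target gene of the glucocorticoid receptor, rose by 2.60 in the raphe (adjusted p = 0.030) and by 2.61 in the cortex (adjusted p = 2.8e-04).

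Against naive samples the mean at 4 h after sham operation was higher by 0.94 in the raphe (adjusted p = 3.5e-11), where Arrdc2 (2.43) and Klf9 (1.54) rose, and by 0.73 in the cortex (adjusted p = 3.1e-10), where Fkbp5 (2.61) and Tsc22d3 (1.24) rose. Injured samples at 4 h against the other injured samples had 0.23 in the raphe (adjusted p = 0.124), where 5 of 22 genes rose, Fkbp5 by 1.93 among them, and 1 fell. In all 1416 probe sets passed there, 554 higher and 862 lower. Without the sample of degraded RNA, raphe injured at 4 h, replicate 1, 17 passed, and the mean was 0.388 (adjusted p = 2.2e-04, 0.091 with an estimated correlation), with 1 gene higher and 0 lower. In the cortex they had 0.53 (adjusted p = 4.3e-10, 2.0e-09 with an estimated correlation), and 7 of 19 genes rose, 11 over the list alone, Fkbp5 by 1.951 and Tsc22d3 by 0.76 among them.

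The hypothesis is that the operation itself may raise these genes through circulating glucocorticoids within hours, which the 0.864 and 0.555 in sham samples would allow. Animals given anaesthesia alone, or with adrenals removed, and sampled at 4 h would test it. On the genes of type A, 7 in the raphe and 6 in the cortex, sham samples at 30 min had 0.0104 in the raphe (naive -0.511 to -0.180) and -0.206 and -0.104 in the cortex (naive -0.542 to -0.294). On all 19 genes the cortex sample at 72 h had -0.402 (naive -0.338 to -0.178).

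Splits of the samples into arbitrary groups gave the chance level of each count. In the raphe over 6 times the real count was 177, and 1 of 100 splits, the real one, was as large, with 10 as the highest other. For injured against naive raphe 570 was reached by 3 of 100 splits, with 1529 as the highest other. A split this far above the real count may point to a structure of the samples, which was not tested; leaving out raphe injured at 4 h, replicate 1, moved the real count to 1893. Sham against naive raphe had 253 (1 of 100, highest other 16), and the time course 91 (1 of 100, highest other 4). For the change over time the real count was 0, so all 100 of 100 splits were as large (highest other 8) and the test says nothing. In the cortex the count over 6 times was 25 (1 of 100, highest other 14), injured against naive 375 (1 of 100, highest other 40), sham against naive 92 (1 of 100, highest other 79), the change 182 (1 of 100, highest other 80) and the time course 206 (1 of 100, highest other 39). The difference between regions had 4 (3 of 100, highest other 8), and the naive regions 2770 (1 of 35, highest other 359).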
